A study of Mus musculus with 6 samples.

How the data were processed

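Small RNA libraries of J1 mouse embryonic stem cells were compared in 6 groups with 1 library each. Per the labels, total RNA was extracted with TRIzol and libraries were made from 1 µg of it with a TruSeq RNA sample preparation kit. The deposited files list distinct read sequences, called tags here, with raw counts per tag and the length of each tag in bases. The unit was checked on the values, which are whole numbers with each sequence listed once and lengths from 18 to 44 bases. The authors state no trimming or filters in the files, and their processing notes name the mm9 genome. Their description of the BIO library says that its raw reads were lost. No gene is assigned to a tag in the deposited files, so the assignment below is a separate one on GRCm38, and the coordinates given are from it.

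Tags of 18 to 26 bases were matched without mismatch to the 1174 hairpins with a Mir symbol among 2202 annotated as miRNA in GENCODE M21. The reference gives hairpins and no mature sequences, so each arm was defined by its most abundant tag, and tags whose start lay within 2 bases of that start were counted. Arms with the same most abundant tag were merged, and tags matching several arms were split evenly among them. Tags that also matched rRNA, mitochondrial rRNA or tRNA, snoRNA, scaRNA, snRNA or Gm42418 were left out. The long nuclear rRNA of the large ribosomal subunit, called large-subunit rRNA here, and nuclear tRNA were not searched. In all, 1265 arms had tags. The window, the restriction to Mir symbols, the merging and the classes left out were chosen after the data had been examined. The first version also left out tags matching other annotated hairpins, and was narrowed because it removed miR-467a and miR-669a tags. Arm names such as miR-10a-5p come from the hairpin symbol and the position of the tag in the hairpin. An arm of a merged group carries the names of all its hairpins, and the miR-465 group stands for miR-465, miR-465b and miR-465c.

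Counts were divided by the microRNA tags of the library and scaled to 1000000 (CPM). Depth was 2155065 microRNA tags for DMSO, 729176 for retinoic acid, 2099662 for BIO, 1428518 for CHIR99021, 1748591 for ddH2O and 1890061 for vitamin C. Shares of a library carry a 95% Clopper-Pearson interval, and ratios of libraries a 95% exact conditional binomial interval from the same method. An arm was compared when it reached 10 CPM in the higher library, and called when the ratio was at least 2-fold and the interval excluded 1. Log2 ratios used a pseudocount of 0.5, and an arm at 0 in a library was given as a bound against 3 counts in that library. With 1 library per group there is no residual spread, so no test between treatments could be made. Correlations of log2 ratios between treatments were set beside simulated unchanged libraries that share a control, with counting error alone or with normal variation between libraries, whose SD of 0.324 on the log2 scale per library was taken from the vehicle libraries after the data were examined.

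The comparisons were retinoic acid, BIO and CHIR99021 against DMSO, vitamin C against ddH2O, CHIR99021 against BIO, and ddH2O against DMSO. The comparisons, the call, the lists and the rule for named arms were fixed before the data were examined. That rule takes arms at 100 CPM or more in the higher library: the 10 with the largest and the 10 with the smallest called ratio, or 5 each for the last 2 comparisons, and up to 4 of the most abundant members of each list. The 20 lists are miR-290-295, miR-302 with miR-367, miR-17-92 and paralogs, let-7, Hox cluster, neural, muscle and heart, endoderm and liver, blood cell, fibroblast and mesenchymal, miR-200, miR-183 with miR-96 and miR-182, Dlk1-Dio3, Sfmbt2 intron, miR-23/27/24, Drosha-independent, p53-linked, miR-15/16, miR-181, and microRNAs with reported targets among Nanog, Oct4 and Sox2. A list's median was taken over members at 10 CPM or more on average, for 3 or more such members, and ranked among 10000 random lists matched on mean expression.

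Alternatives fixed with them were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), counts scaled to all tags, other minimum levels, tags of several microRNAs or counted once left out, untemplated 3' ends of up to 3 bases counted, and the other vehicle library in correlations. Alternatives added after the data had been examined were the most abundant tag of each arm alone, arms with a uniform 5' end, tags of 22 to 24 bases, the other vehicle library as control, leaving out tags of other annotated hairpins, and a different vehicle library for each inhibitor in the overlap of calls. Counting was tested on simulated data: of 400 simulated arms, 0 were counted wrongly. Libraries were also simulated at the real depths with counting error alone, which is the error that the intervals assume. In these, 96 to 99% of 4-fold and 89 to 94% of 2.5-fold differences were recovered. At most 1 unchanged arm was called per comparison, and the intervals covered 95.2 to 96.7% of true ratios. This checks the calculation and not how often libraries that vary would be called. The largest log2 error of the scalings on simulated counts was 0.0053 for TMM and 0.028 for median-of-ratios. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3.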

Results

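Small RNA was sequenced from J1 mouse embryonic stem cells, a line adapted here to gelatin and kept in leukemia inhibitory factor. The cells were treated for 24 h with 1 µM retinoic acid, 1 µM BIO, 3 µM CHIR99021 or 50 µg/ml vitamin C, or with 1 µL of a vehicle, DMSO or ddH2O. Retinoic acid induces differentiation of embryonic stem cells, BIO and CHIR99021 inhibit the kinase GSK3, and vitamin C is a cofactor of dioxygenases that demethylate histones and oxidise methylated DNA. There was 1 library per group and 6 libraries in all, with no replicates, so no p-value was possible. Each ratio below carries a 95% exact conditional binomial (Clopper-Pearson) interval that covers counting error only. Reads without molecular identifiers are not independent molecules, and variation between cultures or library preparations is in none of these intervals.

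The libraries held 18870345 tags for DMSO, 19373152 for retinoic acid, 22258922 for BIO, 23758363 for CHIR99021, 20362550 for ddH2O and 20600614 for vitamin C. Tags from microRNAs made up 11.4% of the DMSO library (Clopper-Pearson interval 11.41 to 11.43%) and 8.59% of the ddH2O library (8.575 to 8.599%). The share was 3.76% after retinoic acid (3.76 to 3.77%), 9.43% after BIO (9.42 to 9.45%), 6.01% after CHIR99021 (6.003 to 6.022%) and 9.17% after vitamin C (9.16 to 9.19%). Between 71.4% and 75.8% of the tags of a library matched none of the RNA classes searched. Nuclear tRNA and large-subunit rRNA were not among these, since the longest rRNA transcript searched had 1849 bases, so rRNA shares are partial and arms such as those of miR-6240 and miR-6236 were not checked against large-subunit rRNA. Another 11.6 to 16.3% matched Gm42418, a gene that overlaps ribosomal RNA repeats. Tags of 18 and 19 bases held 10.9% of the DMSO, 14.4% of the retinoic acid, 8.01% of the BIO, 15.8% of the CHIR99021, 10.99% of the ddH2O and 18.7% of the vitamin C library.

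MicroRNA levels are given for each hairpin arm, 5p or 3p, as its count scaled to 1000000 microRNA tags in the library (CPM). A count of 0 allowed up to 1.39 CPM in DMSO, 4.11 in retinoic acid, 1.43 in BIO, 2.1 in CHIR99021, 1.72 in ddH2O and 1.59 in vitamin C, taking 3 counts as the floor. An arm was called higher or lower when it differed at least 2-fold, its interval excluded 1 and the higher library reached 10 CPM. Positions are on the GRCm38 build. Lists of microRNAs are given by the number of called arms, the median log2 ratio of measured arms, and the percentile of that median among 10000 random lists of the same size and matched expression. The percentile describes these libraries and is not a test between treatments.

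The comparison of ddH2O with DMSO, which mixes vehicle, culture and library preparation, shows how far libraries without an active compound lay apart. The stem cell cluster miR-290-295 was alike in both, at 272761 CPM in ddH2O and 291811 CPM in DMSO, with a median log2 ratio of 0.00 over 14 arms and none called. The hypoxia-linked miR-210-3p was 2.94-fold higher in ddH2O (2.79 to 3.11), at 2634 against 895 CPM. The muscle and heart list was higher, with miR-1a-3p 2.05-fold (1.96 to 2.14) and miR-499-5p 2.63-fold (2.34 to 2.96) called among 3 arms and a median of 1.03 (percentile 99.7). MiR-152-3p was 2.44-fold higher (2.29 to 2.59) and miR-10a-5p, from the Hoxb cluster, 2.39-fold higher (2.22 to 2.58). MiR-296-3p showed the lowest ratio among arms at 100 CPM or more, 4.75-fold lower (4.30 to 5.26) at 257 against 1220 CPM.

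In all, 24 of 484 arms were higher and 11 lower in ddH2O. Further arms at 100 CPM or more were miR-449c-5p, 2.26-fold higher (1.76 to 2.93), miR-92a-2-5p, 3.13-fold lower (2.95 to 3.32), miR-149-3p, 2.47-fold lower (1.92 to 3.21), and the mirtron miR-877-5p, 2.44-fold lower (2.21 to 2.69). The fibroblast and mesenchymal list had a median of 0.49 (percentile 99.6, 1 of 12 arms higher) and the p53-linked list one of 0.63 (percentile 99.6, 1 of 8 arms higher). The Dlk1-Dio3 imprinted cluster, a maternally expressed group of microRNAs on chromosome 12, had a median of -0.11 with none of 76 arms called, yet a percentile of 0.01. Among 255 arms at 100 CPM or more, 81.6% lay within 1.5-fold and the SD of the log2 ratios was 0.47. TMM scaling moved all ratios by -0.11 and median-of-ratios scaling by -0.09. Either gave 20 higher and 20 lower, and miR-1a-3p was at 0.92 and 0.94 under these. With counts scaled to all tags of a library the shift was -0.41, with 9 higher and 44 lower, and miR-1a-3p (0.62), miR-10a-5p (0.85), miR-152-3p (0.87), miR-449c-5p (0.76) and miR-499-5p (0.98) were under 2-fold on the log2 scale.

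Retinoic acid against DMSO asks which microRNAs accompany induced differentiation. The Hox cluster list had the highest median of the 20 lists, 6.88: its miR-10a-5p, in the Hoxb cluster (chromosome 11, 96317186 to 96317207), stood at 57226 against 484 CPM, 118-fold higher (111 to 126). The stem cell cluster miR-290-295 was lower in sum, at 168349 against 291811 CPM, 1.73-fold less. MiR-219a-2-3p, known from oligodendrocytes, was 48.2-fold higher (41.4 to 56.3) at 4025 against 83.5 CPM. MiR-217-5p, known from pancreas, was at 341 CPM after retinoic acid and at 0 in DMSO, at least 245-fold higher against the floor of the DMSO library. In all, 177 of 535 arms were higher and 41 lower.

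Of 7 measured Hox cluster arms, 5 were higher and 1 lower. Beside miR-10a-5p these were miR-10a-3p, 149-fold higher (49.9 to 729), miR-10b-5p of the Hoxd cluster, 11.6-fold higher (6.51 to 22.1), and both arms of miR-615, which lies in the Hoxc cluster. The miR-615 arms were at 0 in DMSO, and miR-615-5p at 83.7 CPM was at least 60.1-fold higher. MiR-196a-1-3p was 2.13-fold lower (1.45 to 3.22), at 42.5 against 90.5 CPM. The median of this list was 6.88 (percentile 100), and 4.50 with the arms at 0 set to their bound.

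In the miR-290-295 list, 4 of 14 arms were lower and none higher, with a median of -0.74 (percentile 0). MiR-290a-3p was 6.43-fold lower (4.01 to 10.98) and miR-290a-5p 2.26-fold lower (2.23 to 2.28), at 42548 against 96000 CPM, while miR-294-3p stood at 23544 against 25358 CPM and miR-291a-3p at 4335 against 4216 CPM. The cluster of miR-302 and miR-367, of the early post-implantation embryo, had a median of 0.05 over 4 arms and a summed level of 0.753 of DMSO, with miR-302a-5p 3.11-fold lower (1.85 to 5.58). The miR-17-92 and paralogous clusters had a median of 0.11 with 1 higher and 2 lower of 22 arms and a summed level of 0.864 of DMSO, and let-7, a family of differentiated cells, one of -0.04 with none of 9 called.

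The miR-181 family had 4 arms higher and 2 lower of 7, with a median of 1.84 (percentile 99.5). MiR-181a-5p was 10.05-fold higher (9.36 to 10.8) at 4620 against 460 CPM and miR-181b-5p 8.45-fold higher (7.96 to 8.97). MiR-181d-5p, the most abundant of them, was 2.34-fold lower (2.28 to 2.40), so the summed level of the family was 0.862 of that in DMSO. The cluster in an intron of Sfmbt2, an imprinted gene, had 30 of 36 arms higher and none lower, with a median of 1.27 (percentile 99.9) and miR-669c-5p at 35603 against 15593 CPM, 2.28-fold higher (2.25 to 2.32). The fibroblast and mesenchymal list had 7 of 12 arms higher and a median of 1.19 (percentile 98.9), with miR-152-3p 5.57-fold (5.23 to 5.94) and miR-21a-5p 2.33-fold (2.26 to 2.39) higher. The fibroblast list was also higher in ddH2O than in DMSO, as given above, and its median against ddH2O was 0.40.

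Lower lists were the miR-23/27/24 clusters (3 of 7 arms, median -0.83, percentile 0.25) with miR-23b-5p 3.34-fold lower (2.69 to 4.18) and miR-27b-5p 3.24-fold lower (2.63 to 4.03). The blood cell list had 2 of 4 arms lower and a median of -1.22 (percentile 0.475), with miR-155-5p 4.17-fold lower (1.32 to 21.2) at 4.11 against 17.2 CPM. The cluster of miR-183, miR-96 and miR-182 had no called arm among 4 and a median of -0.69 (percentile 1.94). Neural microRNAs went both ways: 7 of 15 arms were higher and 2 lower, with a median of 0.62 (percentile 69.5), miR-138-5p 10.8-fold higher (8.92 to 13.05) and miR-124-3p, a microRNA of neurons, 2.37-fold lower (2.19 to 2.57).

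In the muscle and heart list miR-1a-3p was 4.55-fold higher (4.34 to 4.76), 1 of 3 arms called, with a median of 0.97 (percentile 74.5). The endoderm and liver list had 3 of 6 arms higher, miR-217-5p, miR-375-3p of pancreatic islets, 6.85-fold (5.42 to 8.70), and miR-122-5p, 2.15-fold (1.39 to 3.29). Its median was 0.80 (percentile 68.1), or 0.78 with miR-217-5p at its bound, while its summed level was 0.756 of DMSO. The p53-linked list had 4 of 8 arms higher and a median of 1.20 (percentile 93.5), with miR-34c-5p 3.42-fold higher (3.32 to 3.52) at 14120 against 4132 CPM, but against ddH2O its median was 0.43. The miR-15/16 family had 5 of 11 higher, a median of 0.98 (percentile 89.8) and miR-503-5p 2.48-fold higher (2.35 to 2.62). Of 5 microRNAs with reported targets among Nanog, Oct4 and Sox2, 3 were higher and 1 lower, with a median of 1.10 (percentile 88.6). Of these, miR-470-5p was 8.05-fold higher (6.33 to 10.3) and miR-134-5p 2.14-fold (2.03 to 2.26), and miR-296-3p was 2.59-fold lower (2.32 to 2.91).

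The Dlk1-Dio3 cluster had 17 of 78 arms higher and 1 lower, with a median of 0.53 (percentile 72.3). The miR-200 family had none of 5 arms called (median 0.09) and the Drosha-independent list had 1 of 9 higher, 1 lower, a median of 0.29 and a summed level of 0.904 of DMSO. Other arms with large ratios were miR-99a-5p, 82.0-fold higher (31.1 to 306), miR-219a-2-5p, 34.5-fold higher (23.4 to 52.8), the X-linked miR-881-3p, 9.94-fold higher (6.69 to 15.1), and the 3p arm of the miR-465 group, 8.84-fold higher (7.14 to 11.01). Lower arms included both arms of miR-708, in an intron of Tenm4, 4.55-fold for 3p (4.04 to 5.14) and 2.84-fold for 5p (2.60 to 3.11). Also lower were miR-149-3p, 3.52-fold (2.31 to 5.61), miR-877-5p, 3.28-fold (2.79 to 3.87), miR-1968-5p, 2.77-fold (1.97 to 3.99), and miR-6539-5p, 2.76-fold (1.94 to 4.05).

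The numbers of arms called after retinoic acid depended on scaling. TMM scaling moved all ratios by -0.50 and gave 100 higher and 91 lower, and median-of-ratios scaling moved them by -0.36 and gave 113 and 72. With counts scaled to all tags the shift was -1.60, with 46 higher and 311 lower. Relative to the TMM shift the medians were 0.77 for the Sfmbt2 cluster, 0.69 for the fibroblast list, 6.39 for the Hox list, -1.24 for miR-290-295 and 0.03 for the Dlk1-Dio3 cluster, those of the miR-302 and miR-367 (-0.45), miR-200 (-0.41), miR-17-92 (-0.38) and Drosha-independent (-0.21) lists turned negative, and miR-21a-5p (0.72), miR-122-5p (0.61), miR-134-5p (0.60), miR-503-5p (0.81) and miR-669c-5p (0.69) were under 2-fold. With all tags as the total, the Sfmbt2 cluster, at -0.33, and the fibroblast list, at -0.42, turned negative, as did the p53-linked list (-0.40), the miR-15/16 family (-0.62), the Dlk1-Dio3 cluster (-1.07), the muscle (-0.63), endoderm (-0.80) and neural (-0.98) lists, the list with targets among Nanog, Oct4 and Sox2 (-0.50), the 4 lists that turned under TMM, and the arms miR-16-5p, miR-21a-5p, miR-122-5p, miR-134-5p, miR-503-5p and miR-669c-5p, while miR-152-3p (0.88), miR-1a-3p (0.58) and miR-34c-5p (0.17) were under 2-fold. Against ddH2O miR-296-3p turned to a log2 ratio of 0.87, and miR-149-3p (-0.49), miR-877-5p (-0.42), miR-290a-5p (-0.86), miR-302a-5p (-0.66), miR-21a-5p (0.63), miR-122-5p (0.73), miR-16-5p (0.89) and miR-134-5p (0.63) were under 2-fold. The Hox median was 5.26 against ddH2O, that of microRNAs with targets among Nanog, Oct4 and Sox2 0.73 and that of miR-200 -0.49. In the same comparison miR-10a-5p was at 5.63, miR-10a-3p at 5.26, miR-138-5p at 2.43, miR-181a-5p at 2.52, miR-181b-5p at 2.42, the 3p arm of the miR-465 group at 2.38, miR-881-3p at 2.32, miR-708-3p at -1.23, miR-375-3p at 1.65, miR-152-3p at 1.19, miR-34c-5p at 1.08 and miR-1a-3p at 1.15. With untemplated 3' ends counted miR-124-3p was at -0.82.

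**Figure D1:**
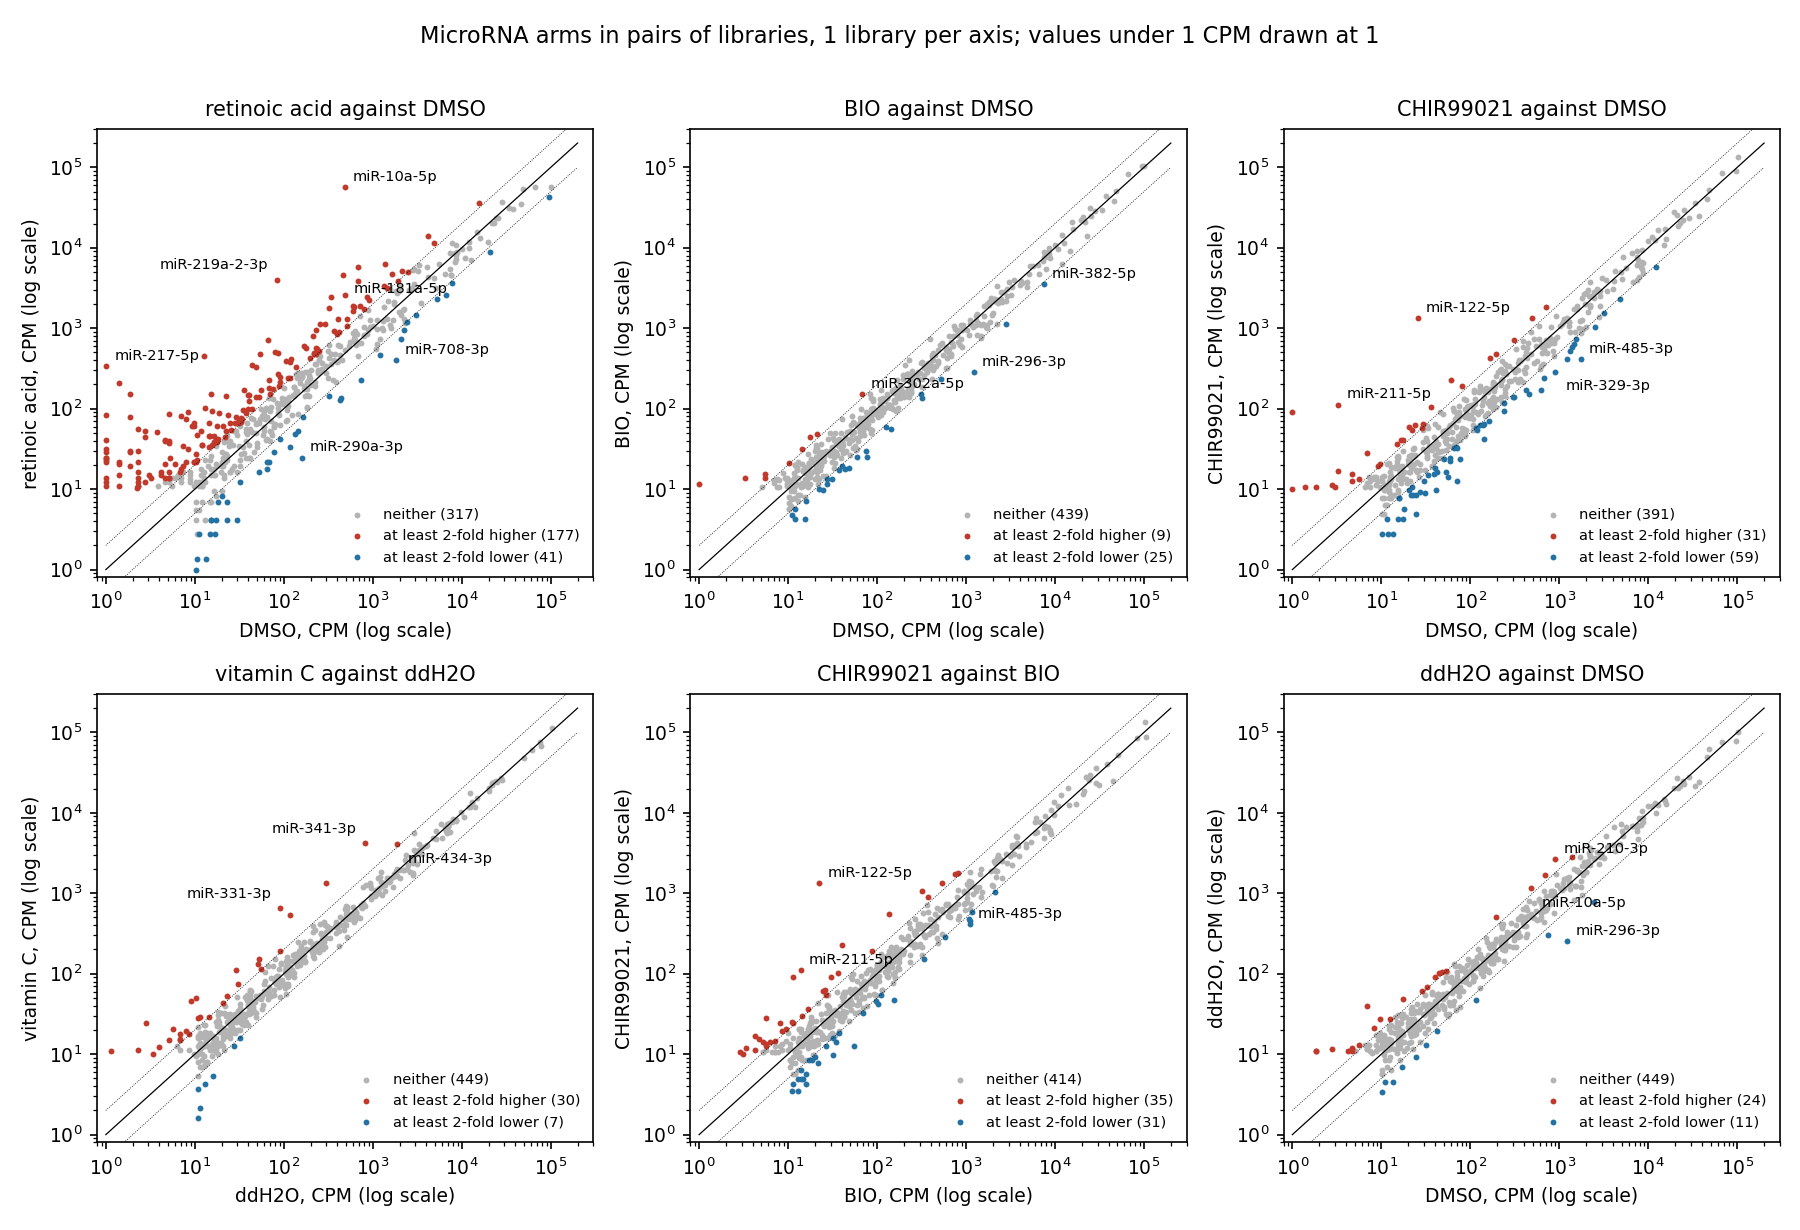
Each panel plots the CPM of every compared microRNA arm in a pair of libraries on log axes, with arms called higher in red, lower in blue and the others in grey, a solid line at equal levels and dotted lines at 2-fold. Retinoic acid against DMSO holds 177 higher and 41 lower arms, and ddH2O against DMSO holds 24 and 11.

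BIO against DMSO asks which microRNAs follow inhibition of GSK3. The Dlk1-Dio3 cluster was lower: its arms summed to 52017 CPM after BIO and 78812 in DMSO, 1.52-fold less. MiR-382-5p of that cluster (chromosome 12, 109733781 to 109733800, in an intron of Mirg) stood at 3530 against 7421 CPM, 2.102-fold lower (2.05 to 2.16). The cluster of miR-302 and miR-367 was higher, with miR-302a-5p 2.20-fold (1.80 to 2.69) at 150.02 against 68.2 CPM and miR-302d-3p 2.25-fold (1.58 to 3.27) at 48.1 against 21.3 CPM. In all, 9 of 473 arms were higher and 25 lower, and 84.5% of 245 arms at 100 CPM or more lay within 1.5-fold (SD of log2 ratios 0.42). The vehicles lay about as far apart, with 24 higher and 11 lower in ddH2O against DMSO (SD 0.47). Unchanged libraries simulated with normal variation at the SD of the vehicles gave 13.6 arms higher after BIO (7 to 20) and 13.5 lower (5 to 21). That simulation was chosen after the data were seen. The higher count was within its range, and the lower count was above it. The 24 arms higher in ddH2O than in DMSO also lay above the simulated 7 to 20. The simulation thus falls short of how far the vehicles lay apart, and a count above its range does not show an effect of BIO.

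Of 73 measured Dlk1-Dio3 arms 9 were lower and none higher, with a median of -0.51 (percentile 0). Among them were miR-136-3p, 2.51-fold lower (2.02 to 3.12), miR-382-3p, 2.45-fold (2.33 to 2.57), miR-377-5p, 2.18-fold (1.75 to 2.72), and miR-540-3p, 2.04-fold (1.78 to 2.34). The abundant miR-323-3p stood at 6212 against 12070 CPM, a log2 ratio of -0.96. The list of miR-302 with miR-367 had 2 of 4 arms higher and a median of 0.93 (percentile 99.97). The miR-290-295 cluster had a median of 0.14 (percentile 98.3) with none of 14 arms called, and the Drosha-independent list one of 0.18 (percentile 97.7) with 1 of 9 lower and a summed level of 0.892 of DMSO. The medians of the other lists lay within the middle 95% of random lists.

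Among other arms, miR-222-3p was 2.22-fold lower (1.99 to 2.47) and miR-296-3p 4.28-fold lower (3.92 to 4.69), the latter at 285 CPM against 257 CPM in ddH2O and a log2 ratio of 0.15 against that vehicle. MiR-6240-5p was 2.37-fold lower (2.06 to 2.73), but at 0.20 with untemplated 3' ends counted, and 99.6% of its tags had 18 or 19 bases, which were not checked against large-subunit rRNA. MiR-211-5p, in an intron of the melanocyte gene Trpm1, was 4.25-fold higher at 13.8 against 3.25 CPM. TMM scaling moved all ratios by 0.11 and gave 13 higher and 19 lower, median-of-ratios scaling moved them by 0.13 and gave 17 and 17, and scaled to all tags the shift was -0.28 with 5 higher and 54 lower. The Dlk1-Dio3 median was -0.40 under TMM scaling and -0.48 against ddH2O over the same 73 arms, where miR-136-3p (-0.94), miR-377-5p (-0.95), miR-382-5p (-0.74), miR-540-3p (-0.78), miR-6240-5p (-0.65) and miR-302d-3p (0.41) were under 2-fold while miR-302a-5p was at 2.07. MiR-377-5p (-0.99) was under 2-fold with median-of-ratios scaling and miR-540-3p (-0.81) with untemplated 3' ends counted. MiR-382-5p (-0.96) and miR-540-3p (-0.92) were under 2-fold with TMM scaling too, as were miR-302a-5p (0.86) and miR-302d-3p (0.89) scaled to all tags. The miR-290-295 and Drosha-independent medians were -0.14 and -0.10 scaled to all tags.

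CHIR99021 against DMSO asks the same of a compound that inhibits GSK3 selectively. The Dlk1-Dio3 cluster was lower here too, at 43142 against 78812 CPM in sum, 1.83-fold less. MiR-485-3p of that cluster (chromosome 12, 109734946 to 109734968, in an exon of Mirg) stood at 410 against 1734 CPM, 4.23-fold lower (3.87 to 4.62). The liver microRNA miR-122-5p (chromosome 18, 65248866 to 65248887) was 51.9-fold higher (39.7 to 69.2) at 1324 against 25.5 CPM, while miR-192-5p, also of that list, stood at 4124 against 5088 CPM. MiR-211-5p (chromosome 7, 64205831 to 64205852) was 34.5-fold higher (16.4 to 87.1) at 112 against 3.25 CPM. In all, 31 of 481 arms were higher and 59 lower.

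Of 74 Dlk1-Dio3 arms 23 were lower and none higher, with a median of -0.84 (percentile 0). They included miR-758-5p, 3.38-fold lower (2.56 to 4.54), miR-329-3p, 3.09-fold (2.78 to 3.45), miR-494-3p, 2.56-fold (2.36 to 2.78), miR-154-3p, 2.47-fold (2.14 to 2.86), and miR-323-3p, 2.103-fold (2.05 to 2.16). The miR-290-295 cluster stood at 342475 CPM with a median of 0.41 (percentile 100) and none of 14 arms called. The Hox list had a median of 0.86 (percentile 99.7), with 1 of 4 arms called, miR-10b-5p, 4.02-fold higher (2.17 to 7.84), but against ddH2O its median was -0.054. In the muscle and heart list miR-1a-3p was 2.37-fold lower (2.20 to 2.57), miR-206-3p 3.01-fold lower (1.63 to 5.98) and miR-499-5p 2.48-fold higher (2.19 to 2.80), with a median of -1.25 (percentile 1.41). MiR-499-5p was 480 CPM here and 510 CPM in ddH2O. The medians of the other lists lay within the middle 95% of random lists.

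The miR-181 family had 3 of 7 arms lower and 1 higher, a median of -0.15 (percentile 46.1) and a summed level of 1.17 times that in DMSO, with miR-181a-5p 3.04-fold lower (2.62 to 3.54) and miR-181b-5p 2.80-fold lower (2.49 to 3.15). In the Sfmbt2 cluster 9 of 29 arms were lower and 1 higher, at a median of -0.13 and a summed level of 1.04 times that in DMSO, with miR-669a/miR-669o-3p 3.56-fold lower (3.11 to 4.10) and miR-466f-2-3p 2.56-fold lower (2.11 to 3.12). MiR-134-5p, reported to target Nanog, was 2.32-fold lower (2.15 to 2.502), and miR-296-3p 2.98-fold lower (2.72 to 3.26), though at a log2 ratio of 0.67 against ddH2O. Higher arms further included miR-331-3p, 3.78-fold (3.08 to 4.67), all of whose tags also match an exon of Vezt, miR-690-3p, 2.52-fold (2.37 to 2.69), miR-6236-5p, 2.75-fold (2.55 to 2.97), miR-3470a-5p, 2.59-fold (2.27 to 2.95), miR-3470b-5p, 2.42-fold (1.99 to 2.94), and miR-3473b-3p, 2.30-fold (2.08 to 2.54), with 85.4% of its tags at 18 or 19 bases. All tags of miR-3473b-3p also match another annotated transcript. MiR-378c-5p was 2.86-fold higher (2.16 to 3.82), but 98.97% of its tags are shared with other microRNAs. Without these its log2 ratio was -2.21, a value near the floor that rests on the few tags left.

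Scaling to all tags moved the ratios of CHIR99021 to DMSO by -0.93, with 5 higher and 267 lower, and the medians of miR-290-295 (-0.52) and the Hox list (-0.061) turned negative. MiR-331-3p (0.99), miR-499-5p (0.38), miR-690-3p (0.41), miR-3470a-5p (0.44), miR-3470b-5p (0.35), miR-378c-5p (0.59), miR-3473b-3p (0.27) and miR-6236-5p (0.53) were then under 2-fold. Median-of-ratios scaling moved them by 0.10 and gave 34 higher and 45 lower, with miR-323-3p at -0.97. The Dlk1-Dio3 median was -0.76 under TMM scaling and -0.77 against ddH2O, where miR-154-3p (-0.73), miR-323-3p (-0.77), miR-466f-2-3p (-0.62), miR-690-3p (0.96) and miR-3470b-5p (0.73) were under 2-fold, miR-331-3p was at 1.33, miR-181a-5p at -2.41, miR-181b-5p at -2.14, miR-1a-3p at -2.28 and miR-211-5p at 7.03.

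**Figure D2:**
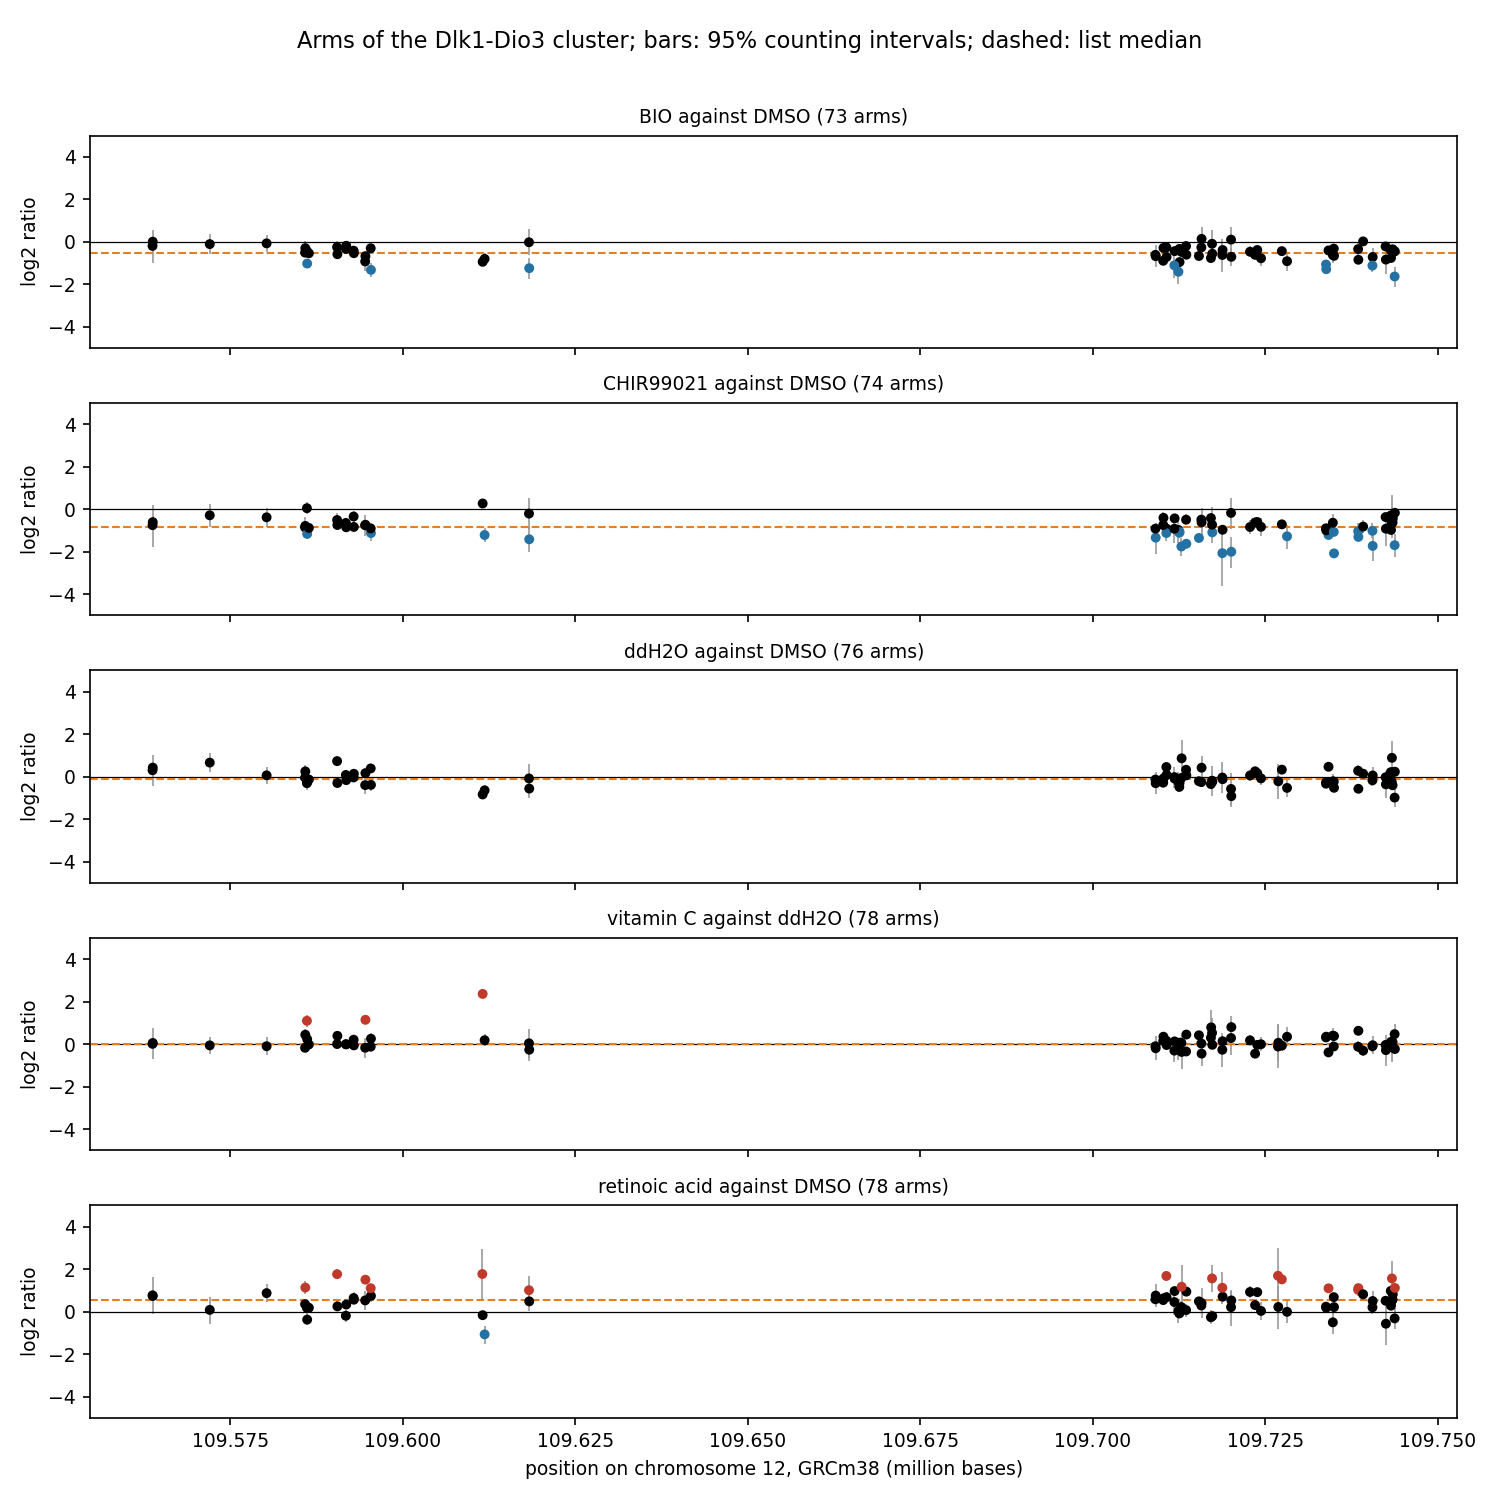
Log2 ratios of the arms of the Dlk1-Dio3 cluster by position on chromosome 12 in 5 comparisons, with arms called higher in red and lower in blue, bars for the 95% counting intervals and a dashed line at the list median. The median was -0.51 for BIO, -0.84 for CHIR99021, -0.11 for ddH2O against DMSO, 0.02 for vitamin C and 0.53 for retinoic acid. The signs for BIO and CHIR99021 held under every scaling, and the median for retinoic acid was -1.07 scaled to all tags.

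CHIR99021 against BIO sets these GSK3 inhibitors side by side at 3 and 1 µM, so dose and compound differ together. The liver microRNA miR-122-5p was 59.2-fold higher after CHIR99021 (44.3 to 80.8), at 1324 against 22.4 CPM. MiR-211-5p was 8.11-fold higher (5.43 to 12.5), at 112 against 13.8 CPM, and was called higher than DMSO after either compound. The Dlk1-Dio3 cluster was lower after CHIR99021 than after BIO, with a median of -0.26 (percentile 0.2), 5 of 72 arms lower and 1 higher, and the 23 of 74 and 9 of 73 arms called against DMSO given above. MiR-485-3p was 2.67-fold lower (2.43 to 2.92) and miR-758-5p 2.43-fold lower (1.81 to 3.29).

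In all, 35 of 480 arms were higher and 31 lower after CHIR99021. The miR-290-295 median was 0.34 (percentile 99.8) with none of 14 arms called, and the Drosha-independent median was -0.55 (percentile 0.9) with none of 9 called and a summed ratio of 1.20. The neural miR-219a-2-3p was 3.24-fold lower (2.49 to 4.27), miR-181a-5p 2.24-fold lower (1.92 to 2.62) and miR-92b-5p 2.47-fold lower (2.26 to 2.70). Higher were miR-331-3p, 5.70-fold (4.48 to 7.34), miR-10a-5p, 2.44-fold (2.23 to 2.67), miR-6240-5p, 4.003-fold (3.49 to 4.60), and miR-6240-3p, 3.36-fold (3.07 to 3.69). With untemplated 3' ends counted miR-331-3p was at a log2 ratio of 1.41 and miR-6240-5p at 1.45. Scaling to all tags moved the ratios by -0.65 and gave 8 higher and 142 lower, with miR-10a-5p at 0.64, and the miR-290-295 median turned to -0.31.

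Of 462 arms compared for both inhibitors, 12 were lower than DMSO after each, and 6 of the 12 belong to the Dlk1-Dio3 cluster. Independent lists would share 3.19. Unchanged libraries simulated against the same DMSO library shared 0.145 on average with counting error alone. They shared 2.61 (middle 95% 0 to 6) when libraries also varied with the SD of the vehicle libraries, a simulation chosen after the data were seen. As given above, that simulation gave fewer higher arms than the vehicles did, so its shared counts may be too low. Higher after each were 4 arms, where independent lists would share 0.364 and the simulations 0.155 and 2.84 (0 to 6): miR-211-5p, miR-211-3p, miR-466d/miR-466n-5p and miR-6962-5p, of which the last 3 were named after their values were seen. MiR-211-3p stood at 0.928 CPM in DMSO, 11.4 after BIO and 91.0 after CHIR99021. Both ratios share the DMSO library, and part of the excess may come from it: 2 of the 12 arms, 1 of them miR-296-3p, were also lower in ddH2O than in DMSO, and of the 4 higher arms miR-466d/miR-466n-5p was also higher there. With BIO set against DMSO and CHIR99021 against ddH2O, a choice made after the data were seen, 6 arms were lower after each where independent lists would share 3.04, with 2 in the Dlk1-Dio3 cluster. With the vehicles exchanged 8 were lower where 4.57 would be shared, with 1 in that cluster, and both arms of miR-211 were among the 3 higher arms in either case. Across 251 arms, which are not independent replicates, the log2 ratios of BIO and CHIR99021 had a Pearson correlation of 0.45 and a Spearman correlation of 0.56, while simulated unchanged libraries against the same DMSO library gave a Pearson correlation of 0.44 with counting error alone and 0.49 (0.39 to 0.59) with variation between libraries. The covariance was 0.135, against 0.00333 simulated with counting error and 0.107 (0.0787 to 0.141) with variation between libraries, so it did not exceed what a shared DMSO library gave in that simulation. With CHIR99021 set against ddH2O instead the Pearson correlation was 0.25, and with BIO set against ddH2O it was 0.10. This was 1 of 6 pairs of treatments computed, and the other Pearson correlations were -0.01 for retinoic acid and BIO, -0.06 for retinoic acid and CHIR99021, -0.12 for retinoic acid and vitamin C, -0.26 for BIO and vitamin C and 0.08 for CHIR99021 and vitamin C.

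Vitamin C against ddH2O asks which microRNAs follow this cofactor. MiR-331-3p was 7.17-fold higher (6.07 to 8.51), at 652 against 90.9 CPM (chromosome 10, 93963783 to 93963803). Within the Dlk1-Dio3 cluster 3 of 78 arms were higher and none lower: miR-341-3p, in an intron of Rian, 5.15-fold (4.87 to 5.45) at 4192 against 814 CPM, miR-434-3p, 2.21-fold (2.12 to 2.31) at 4118 against 1862 CPM, and miR-540-5p, 2.14-fold (1.77 to 2.60). The cluster as a whole had a median of 0.02 (percentile 76.7). No arm at 100 CPM or more was called lower.

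In all, 30 of 486 arms were higher and 7 lower, and 88.5% of 260 arms at 100 CPM or more lay within 1.5-fold (SD of log2 ratios 0.48). The vehicles lay about as far apart, with 24 higher and 11 lower in ddH2O against DMSO. There 81.6% of arms at that level lay within 1.5-fold (SD 0.47). Higher arms after vitamin C included miR-143-5p, of smooth muscle and mesenchyme, 2.88-fold (2.27 to 3.68), miR-345-5p, 2.58-fold (2.02 to 3.32), and miR-692-3p, 2.07-fold (1.62 to 2.66). MiR-3473b-3p was 4.52-fold higher (4.11 to 4.98), miR-3473e-5p 4.60-fold (3.96 to 5.37) and miR-378c-5p 3.83-fold (2.81 to 5.30). For miR-3473e-5p 96.1% of the tags are shared with other microRNAs, and for miR-378c-5p 98.97%. Without these the log2 ratios of the 2 arms were 4.71 and 2.70, values that rest on the few tags left. The miR-290-295 cluster had a median of 0.07 (percentile 98.7) with none of 14 arms called. The muscle and heart list had a median of -0.75 (percentile 0.13) and the miR-200 family, of epithelial cells, one of -0.40 (percentile 0.62), with no arm called in either. Against DMSO these 2 medians were 0.28 and 0.16. The medians of the other lists with 3 or more measured arms lay within the middle 95% of random lists.

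All of the tags of miR-331-3p also match an exon of Vezt, and with untemplated 3' ends counted its log2 ratio was 2.02, and against DMSO it was at 3.43. With those ends counted miR-341-3p was at 0.50, under 2-fold, and against DMSO miR-341-3p was at 1.53 and miR-540-5p at 0.79.

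**Figure D3:**
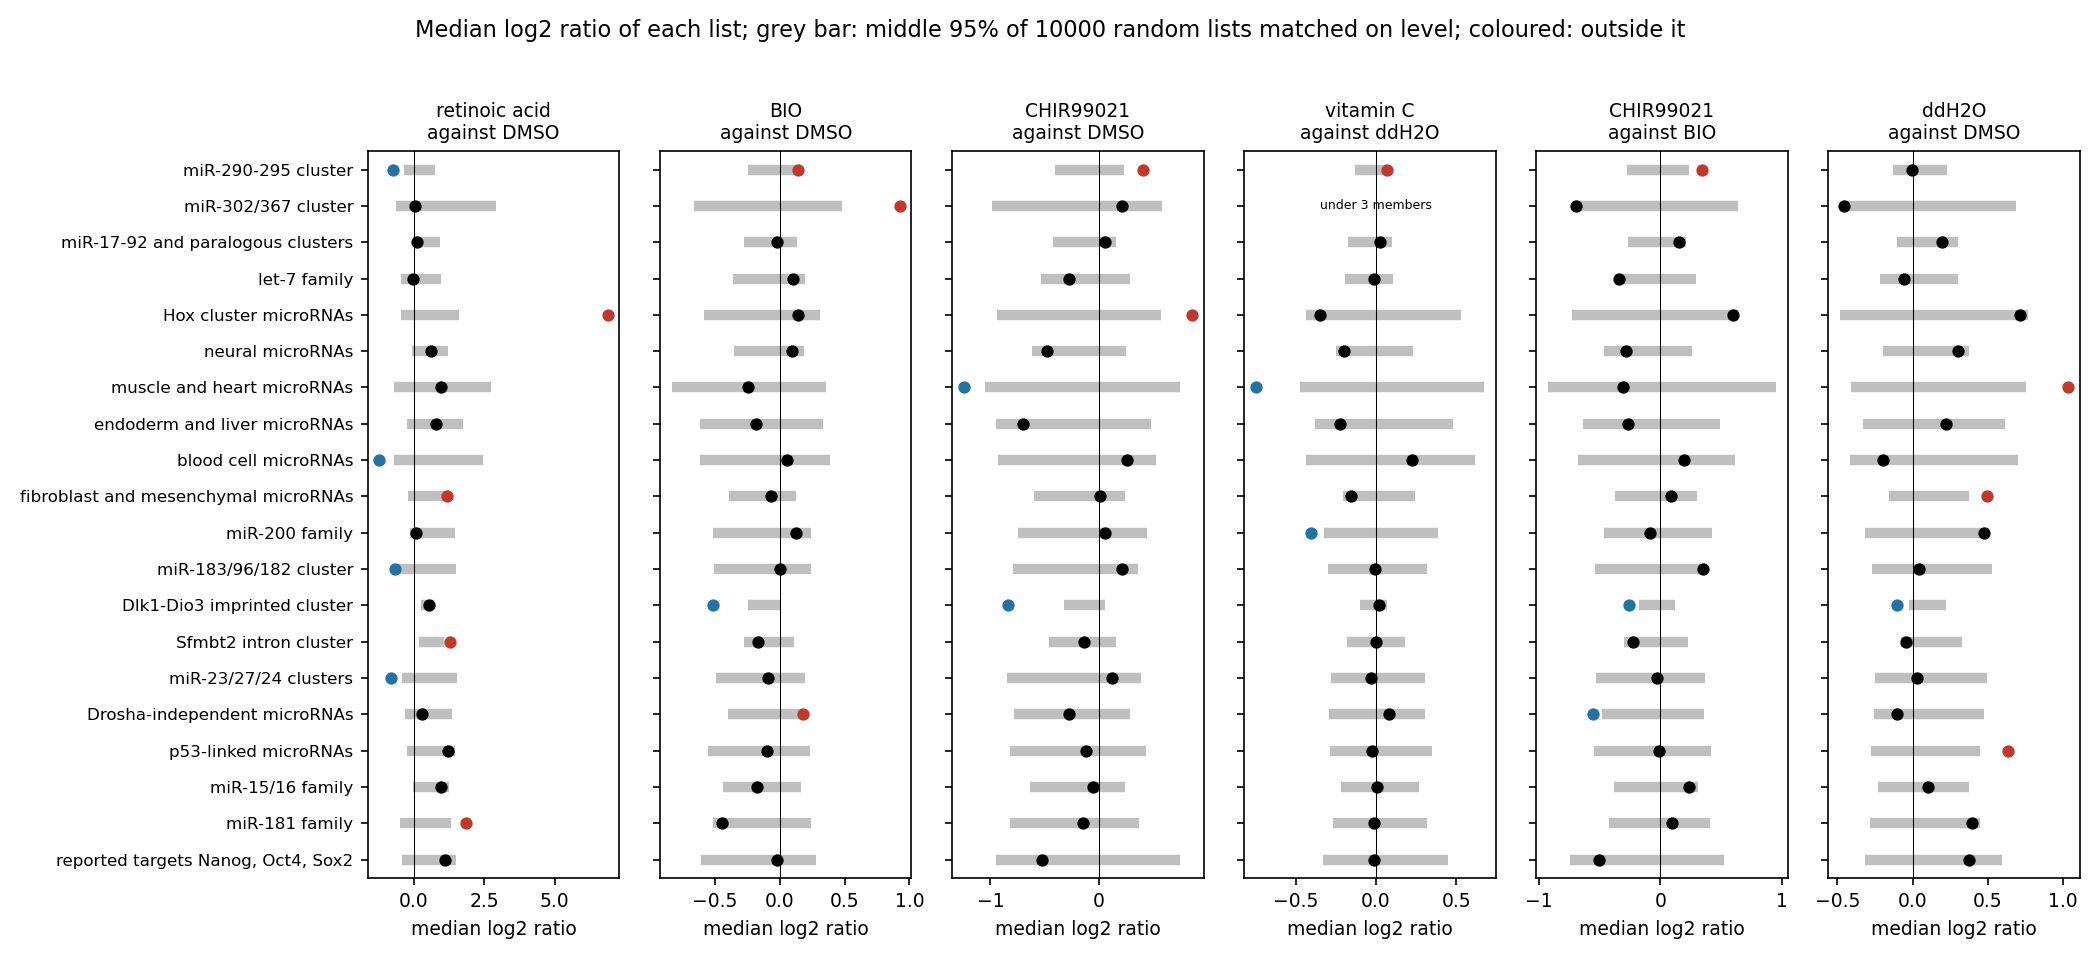
Median log2 ratio of the 20 fixed lists in each comparison where 3 or more arms were measured, 119 medians in all, with a grey bar for the middle 95% of 10000 random lists and points in red or blue where the median lies outside it. The Hox list after retinoic acid is drawn at 6.88, and is 4.50 with arms at 0 set to their bound. When counts are scaled to all tags, 7 of the 26 medians outside the grey bars change sign, namely miR-290-295 for BIO, CHIR99021 and CHIR99021 against BIO, Drosha-independent for BIO, Hox for CHIR99021, and Sfmbt2 and fibroblast for retinoic acid, as do 46 of the 93 inside them.

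**Figure D4:**
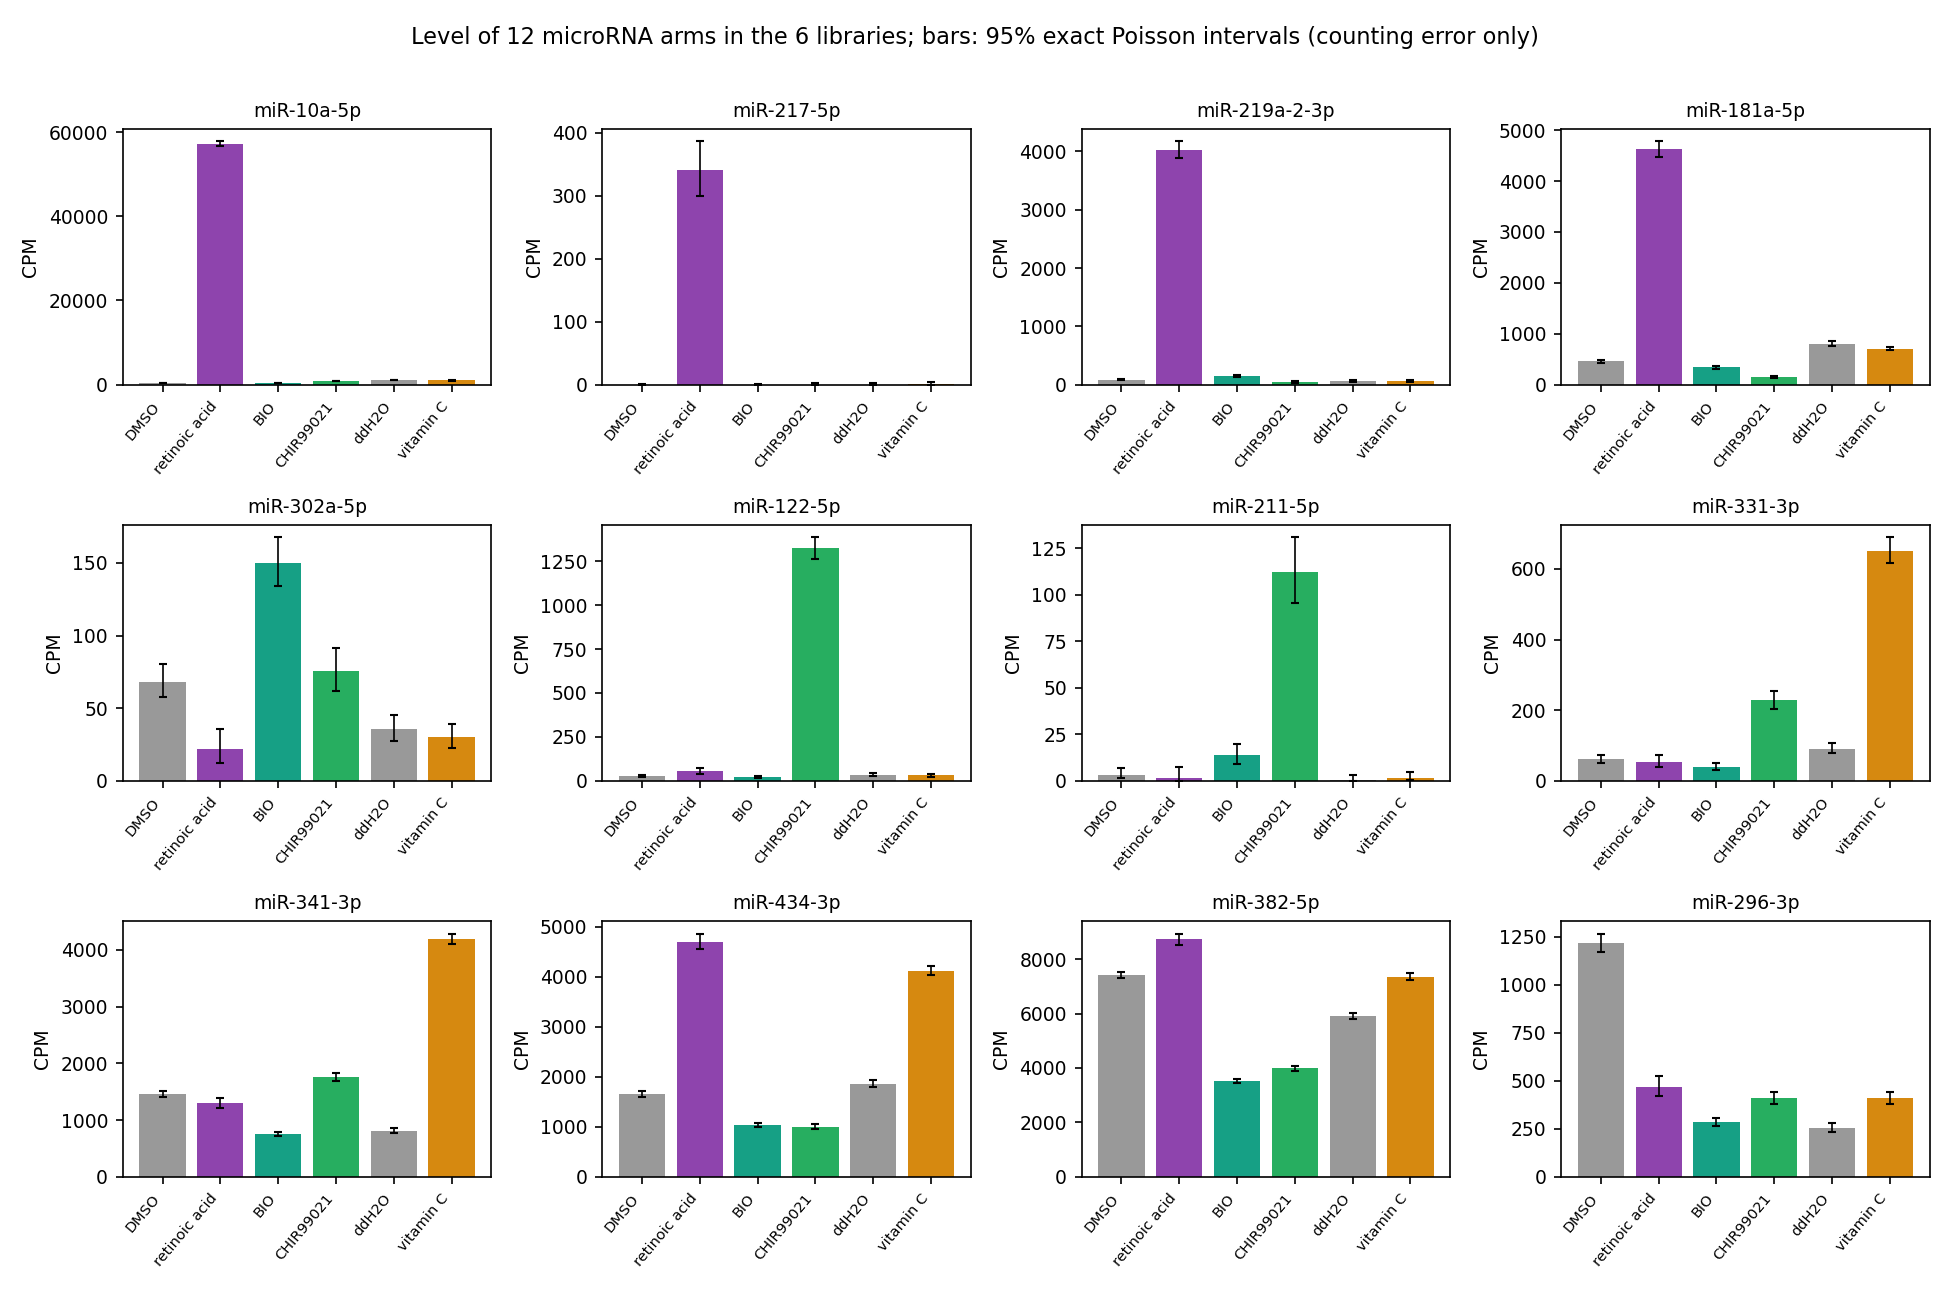
Level in CPM of 12 microRNA arms in the 6 libraries, 1 bar per library, with 95% exact Poisson intervals for counting error. MiR-10a-5p reaches 57226 CPM after retinoic acid, miR-122-5p 1324 CPM after CHIR99021, miR-331-3p 652 CPM after vitamin C, and miR-296-3p 1220 CPM in DMSO.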

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

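The tests of the Dlk1-Dio3 cluster against the ddH2O library were chosen only after the result was seen, and the 3 patterns weighed here were picked for their size after all comparisons had been made.

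Some data outside the microRNA comparisons rose above the vehicle library, by at least 2-fold. Tags of Mir hairpins outside the counted windows made up 0.0477% of the vitamin C library and 0.0178% of ddH2O, with 5959 of 9829 such tags from Mir341-3p in vitamin C and 768 of 3634 in ddH2O, but over DMSO the share was 1.78-fold. Tags matching annotated rRNA made up 0.381% of the retinoic acid library and 0.158% of DMSO, without large-subunit rRNA, which was not searched. Among abundant tags that match no searched RNA, the tag ranked 2 held 2.76% of the retinoic acid library against 0.783% of DMSO, and the tag ranked 15 held 1.21% against 0.145%, or 0.483% in ddH2O. The tag ranked 6 held 1.35% of the vitamin C library against 0.514% of ddH2O, but 1.07% in DMSO, and the tag ranked 12 held 0.669% of the CHIR99021 library against 0.325% of DMSO, but 0.557% in ddH2O, so both rises were under 2-fold against the other vehicle.

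The Dlk1-Dio3 cluster was lower after BIO and after CHIR99021, with medians of -0.51 and -0.84. A DMSO library that stands apart is argued against as the sole account. Against ddH2O the medians, over the 75 and 76 arms measured there, were -0.49 for BIO and -0.77 for CHIR99021. The middle 95% of random lists was -0.41 to -0.15 and -0.46 to -0.10. Against DMSO the random lists lay higher, at -0.25 to 0.01 and -0.32 to 0.06. The cluster thus lay closer to them with ddH2O as control, and part of its distance may come from the DMSO library. A linear trend with GC content and tag length is argued against too, since after its removal over the other arms the medians were -0.49 (-0.21 to 0.06) and -0.84 (-0.35 to 0.06). The GC part of the fit could move little. The median GC content of the cluster was 47.6 and 47.7% against 47.8% in other arms, and the log2 slopes were 0.0143 and -0.000848 per 10% GC. An effect of GSK3 inhibition is 1 open explanation, but with 1 library per group it cannot be separated from differences between cultures, such as drift in imprinting, or between library preparations, neither of which was tested. Random lists of unrelated arms also understate how far a jointly transcribed cluster may vary: ddH2O against DMSO put it at the 0.01 percentile with a median of -0.11.

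Arms miR-378c-5p, miR-5126-3p, miR-331-3p, miR-3473a-3p, miR-3473b-3p, miR-182-3p and miR-361-3p were higher after both CHIR99021 and vitamin C, 7 where 1.25 would coincide by chance. Tags shared between microRNAs do not account for the set, since 5 of the 7 were still called in both without such tags. An excess of 18 and 19 base tags stays open, with 4 of 7 still called without those lengths: both libraries exceeded their vehicle over all tags, but among microRNA tags the share was 3.33% in CHIR99021 against 4.95% in DMSO, and 4.73% in vitamin C against 3.39% in ddH2O. Open too are fragments of other transcripts, with 3 of 7 taking 50% or more of their tags from sequences that also match another transcript, against 23.8% of 562 arms. Such a match cannot tell a fragment from a microRNA that lies in an exon, as miR-331-3p does in Vezt. The counts are too few to decide either, and no biological explanation common to both compounds was tested.

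MiR-122-5p and miR-211-5p were higher after CHIR99021 than in any other library. Amplification of a single sequence cannot account for most miR-122-5p tags, since the most abundant tag held 44.3% of them. The median of 210 reference arms was 61.1%. The miR-122-5p tags after CHIR99021 were of 7 distinct sequences, and amplification of several sequences together was not tested. For miR-211-5p the test cannot decide. Its most abundant tag held 86.2%, above that median but under 94.9%, the upper limit of the middle 95% of the reference arms. A share under that limit does not exclude amplification, and the shares of both arms in other libraries were not compared. RNA of liver cells stays open for miR-122-5p and cannot be told apart from a response to CHIR99021, although of the liver and endoderm arms under 50 CPM in DMSO, 0 of 3 were called higher and each had a lower level after CHIR99021, with ratios of 0.446 for miR-194-2-5p (0.276 to 0.697), 0.603 for miR-215-5p (0.281 to 1.21) and 0.609 for miR-375-3p (0.415 to 0.880). The bound written beforehand would have read this as excluding liver RNA, and it was set aside after the result was seen, since the level these arms kept after CHIR99021, summed, is still 4.34% of the gain in miR-122-5p and could hold a smaller contribution, their ratio to miR-122-5p in liver is in none of the tables, and the 5088 CPM of miR-192-5p in DMSO would hide a small share. A response to CHIR99021 stays open for both arms, and miR-211-5p was also called higher after BIO, but culture and library preparation remain confounded with treatment.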

How the results depend on the processing

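The tests with only the most abundant tag of each arm, uniform 5' ends, tags of 22 to 24 bases, the other vehicle library as control, and tags of other annotated hairpins left out were chosen only after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out in turn. Counting only tags identical to an annotated mature sequence was not run, since the reference gives hairpins alone.

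Counts of called arms are given as higher and lower. For retinoic acid, 177 and 41 became 100 and 91 with TMM scaling, 113 and 72 with median-of-ratios scaling, 46 and 311 scaled to all tags, and 80 and 20 with a minimum of 100 CPM. For BIO, 9 and 25 became 5 and 54 scaled to all tags, 1 and 8 with a minimum of 100 CPM, and 21 and 47 against ddH2O, where 4 and 12 arms were shared with the comparison to DMSO. With the other vehicle the shared arms were 125 of 177 and 23 of 41 for retinoic acid, 17 of 31 and 30 of 59 for CHIR99021, and 21 of 30 and 1 of 7 for vitamin C. The higher count for BIO was 17 with median-of-ratios scaling, 19 with no minimum and 22 with only the most abundant tags, and the lower count was 16 with untemplated 3' ends. For CHIR99021, 31 and 59 became 5 and 267 scaled to all tags and 10 and 26 with a minimum of 100 CPM. For vitamin C, 30 and 7 became 10 and 0 with a minimum of 100 CPM, the lower count was 12 with no minimum, and the higher count was 16 with tags of 22 to 24 bases. For CHIR99021 against BIO, 35 and 31 became 8 and 142 scaled to all tags and 11 and 10 with a minimum of 100 CPM, and the higher count was 16 with tags of 22 to 24 bases. For ddH2O against DMSO, 24 and 11 became 9 and 44 scaled to all tags and 8 and 4 with a minimum of 100 CPM, and the lower count was 20 with TMM and with median-of-ratios scaling. The minimum of 100 CPM lowers counts by its construction, since fewer arms are compared. The shift of all ratios scaled to all tags follows from the microRNA shares of the libraries. For the other changes the cause was not tested. All 12 counts stayed within 1.5 times with tags of several microRNAs left out, tags counted once left out, arms of a uniform 5' end, and tags of other hairpins left out.

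With counts scaled to all tags, 7 of the 26 list medians outside the middle 95% of random lists changed sign, as did 46 of the 93 inside it. The 7 were, for retinoic acid, the fibroblast list (-0.42) and the Sfmbt2 cluster (-0.33), for BIO miR-290-295 (-0.14) and the Drosha-independent list (-0.10), for CHIR99021 miR-290-295 (-0.52) and the Hox list (-0.061), and for CHIR99021 against BIO miR-290-295 (-0.31). Under that scaling the retinoic acid ratios of miR-122-5p (-0.49), miR-21a-5p (-0.38), miR-669c-5p (-0.41), miR-669a/miR-669o-3p (-0.034), miR-467a/miR-467d-3p (-0.14), miR-16-5p (-0.58), miR-503-5p (-0.29) and miR-134-5p (-0.50) also reversed. With the other vehicle as control, 3 of 19 medians outside that range changed sign, and 24 of 60 inside it did. The 3 were, for CHIR99021, the Hox list (-0.054) and, for vitamin C, the muscle list (0.28) and the miR-200 family (0.16). A change of control shifts each arm by its ratio between the vehicles. The medians of ddH2O against DMSO were 0.71 for the Hox list, 1.03 for the muscle list and 0.48 for the miR-200 family. TMM scaling turned 0 of 26 and 16 of 93, and median-of-ratios scaling 0 and 14. With the other vehicle miR-296-3p reversed for retinoic acid (0.87), BIO (0.15) and CHIR99021 (0.67), and miR-499-5p for CHIR99021 (-0.087), as these arms differ between the vehicles. MiR-6240-5p reversed for BIO (0.20) with untemplated 3' ends, which add its tags ending in an untemplated G. MiR-378c-5p did so for CHIR99021 (-2.21) without shared tags, where few tags were left. Of 118 called ratios of named arms, 108 stayed at least 2-fold with TMM scaling, 107 with median-of-ratios scaling, 86 scaled to all tags, 113 with only the most abundant tags and 112 with untemplated 3' ends, and 67 of 93 with the other vehicle.

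The share of microRNA tags was 11.8, 3.86, 9.75, 6.21, 8.88 and 9.51% with tags counted once left out, for DMSO, retinoic acid, BIO, CHIR99021, ddH2O and vitamin C in that order. It was 7.29, 2.47, 6.34, 3.92, 5.63 and 5.94% with only the most abundant tags, and 12.8, 4.45, 10.7, 6.86, 9.76 and 10.4% with untemplated 3' ends. Each of these changes follows from the tags left out or added. The correlation of retinoic acid and BIO was -0.36 with BIO and -0.15 with retinoic acid set against ddH2O, that of retinoic acid and CHIR99021 -0.30 and -0.19 likewise, and that of BIO and CHIR99021 0.25 and 0.10. Depth limits the retinoic acid library most, where 3 counts are 4.11 CPM, against 1.39 CPM in DMSO.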

Other observations

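MicroRNA arms ended in untemplated bases in every library. Tags with ends of 1 to 3 bases beyond the hairpin were taken as a share of a total that holds them and the counted microRNA tags. They made up 10.6% in DMSO, 15.5% in retinoic acid, 11.6% in BIO, 12.3% in CHIR99021, 11.99% in ddH2O and 11.5% in vitamin C. A single untemplated A or T was the usual form, as is known for mature microRNAs, at 3.62 and 3.75% in DMSO. Shares of a single base are of the counted microRNA tags together with all tags that end in 1 untemplated base. A single G held 0.632% in DMSO and 4.20% in retinoic acid, and 95.96% of those G ends in retinoic acid came from miR-6240-5p, with 33693 such tags against 10528 in DMSO. These tags are outside the counts of the comparisons. They were not checked against large-subunit rRNA, so it is open whether they, and the higher share of untemplated ends in retinoic acid, are of microRNAs.

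The level of the Dlk1-Dio3 cluster among all microRNA tags was 7.88% in DMSO, 7.19% in ddH2O, 8.04% in vitamin C, 10.7% in retinoic acid, 5.20% in BIO and 4.31% in CHIR99021. The miR-290-295 cluster held 29.2% in DMSO, 27.3% in ddH2O, 28.1% in vitamin C, 16.8% in retinoic acid, 30.8% in BIO and 34.2% in CHIR99021. Small nucleolar RNA made up 1.33% of all tags in DMSO, 1.35% in BIO, 0.963% in ddH2O, 0.929% in CHIR99021, 0.844% in vitamin C and 0.677% in retinoic acid.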
